A study of Mus musculus with 6 samples.

How the data were processed

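RNA from mouse macrophages was measured on 6 one-colour Affymetrix arrays, per the labels from total RNA extracted with TRIzol and hybridised as biotinylated cRNA. The samples were grouped by their titles into wild type with medium (1 array), wild type with LPS (1 array), wild type of the Trib1 line with LPS (2 arrays) and Trib1 knockout with LPS (2 arrays). The deposited values are probe set intensity values on a linear scale, made per the labels by the authors with MAS5, whose version and scaling target are not stated. The mean without the lowest and highest 2% was 500 on both arrays of the LPS pair and 101, 99.9, 95.5 and 107 on wild type 1, knockout 1, wild type 2 and knockout 2, so the deposited arrays were scaled to different levels. The table holds 45101 probe sets. The 64 control probe sets were left out, which leaves 45037, of which 34945 list 1 gene symbol, 932 several and 9160 none. The reference table held the gene identifiers of 34741 of the single-gene probe sets and not those of 204.

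Each array was scaled to a common trimmed mean of 234. Values under the pooled 40th percentile of the 6 arrays (29.9) were set to it as a floor, and log2 was taken. For an array, signal over background sets what can be measured: between 57.9% and 63.0% of probe sets lay above the floor on each array, and a fold against a group with every array under the floor is given as a lower bound. For LPS against medium, with 1 array each, no test was made: a probe set was induced at a ratio of at least 4 and repressed at its inverse, with the higher value above the floor. Each list's median log2 ratio was placed among 10000 random lists of the same size and similar mean level.

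Knockout-labelled and wild-type Trib1-line arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend; residual degrees of freedom 2, prior 3.68), two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. Probe sets above the floor on at least 2 of the 4 arrays were tested. The same fit was adjusted over the LPS-induced probe sets alone and over each fixed gene list alone, with no adjustment across the lists. The list of LPS-induced probe sets comes from arrays outside the fit, except where the LPS array of the LPS pair is added to it as an alternative. A count of probe sets with both arrays of a genotype at least 2-fold above both of the other needs no model and was set beside the same count for the other two splits of the arrays. Lists were tested as sets with camera (preset correlation 0.01, then estimated) and fry, with Benjamini-Hochberg adjustment over 22 lists, using for each gene the probe set with the highest mean over the 6 arrays. The 150 genes on each side of Trib1 were compared with all others by Fisher's exact test. Correlations between differences were taken across probe sets. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

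The samples' groups, tests, lists and naming rule were fixed before the data were examined. The lists were C/EBP targets, cytokines and chemokines, NF-kB pathway and feedback, interferon-stimulated genes, alternative activation, eicosanoids, nitric oxide and oxidative burst, antigen presentation, Tribbles family and partners, cell cycle, sterols and lipids, glycolysis and hypoxia, TLR receptors and adaptors, proteases and inhibitors, macrophage identity, markers of neutrophils, eosinophils and mast cells, B cells, T and NK cells, dendritic cells and mesothelial or stromal cells, and sex-linked genes. The genes named were Trib1, then the 10 largest rises and 5 largest falls past the LPS rule with up to 4 passing members of each list. For the genotypes they were the 10 genes in each direction past the threshold, or, since fewer than 5 passed, the 10 with the smallest p among genes with separate groups and at least a 2-fold difference, said not to pass. The same rule was used for LPS-induced genes. From each list up to 4 members that passed over the list alone were named, or else the 2 with the smallest p, and all C/EBP targets. Where more than 4 passed, the others were named too, after their values were seen. Only probe sets with 1 gene symbol were named, and other probe sets of a named gene are given where their sign differs.

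The alternatives were the values as deposited, quantile normalization, floors at the 25th and 60th percentiles, log2 of the value plus 16 without a floor, no filter (above the floor on at least 1 array), the number of the labels as a block, each of the 4 arrays left out in turn, the LPS array of the LPS pair as an added wild type, a prior without a trend, 1 probe set per gene, and fold rules of 2 and 8. For LPS, each wild-type Trib1-line array was also put in place of the LPS array, and limma was run on the medium array against 3 wild-type LPS arrays. The methods were tested on simulated data made from these arrays. The 4-fold rule recovered 192 of 200 probe sets changed 16-fold and passed 737 of 44837 unchanged ones (1.64%). In 5 simulations, limma over all probe sets recovered 0% of 2-fold, 6.97% of 4-fold and 39.1% of 16-fold changes with 9 false calls. Over the LPS-induced list alone it recovered 26%, 94% and 100%, with 3 false calls. In the data 223 and 212 probe sets passed the 4-fold rule between arrays of the same genotype and treatment. The simulated spread was thus larger, and these shares may not hold for the data. No sample was left out.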

Results

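RNA levels were measured on 6 one-colour Affymetrix mouse arrays, 1 per sample, all from macrophages. The first 2 arrays hold wild-type macrophages given medium (n = 1) or lipopolysaccharide (LPS, a bacterial cell wall component sensed through a Toll-like receptor; n = 1). Per the series description they define LPS-inducible genes, and they are called the LPS pair here. The other 4 arrays hold LPS-treated macrophages of wild-type (n = 2) and Trib1-deficient (n = 2) mice, each numbered 1 and 2. These serve to compare the genotypes and are called the Trib1-line arrays. The labels give no source of the macrophages, LPS dose, time, strain, sex or age. They do not say whether arrays of a genotype come from separate animals or cultures, so p-values measure only the spread between these samples. An exact permutation test of 2 arrays against 2 cannot go below a two-sided p = 0.333, so genotypes were compared with limma, which pools the spread across probe sets. After scaling, the share of probe sets above the floor was 58.5% and 57.9% on the medium and LPS arrays of the LPS pair, 59.2% and 63.0% on wild type 1 and 2, and 58.6% and 62.8% on knockout 1 and 2. Pearson correlations between arrays lay between 0.935 and 0.976 across probe sets, which are not independent replicates. The number of arrays limits the precision of every value.

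Trib1, a pseudokinase that brings C/EBP transcription factors to a ubiquitin ligase, has 2 probe sets on the array. On 1424880_at the scaled intensity was 383.5 in medium and 189.3 after LPS in the LPS pair. It was 17.9 and 17.5 on the wild-type Trib1-line arrays, both under the floor of 29.9, and 88.1 and 20.9 on the knockout-labelled arrays. On 1424881_at the wild-type values were 20.2 and 63.0 and the knockout-labelled values 32.3 and 38.7, a log2 difference of -0.30 (SE 0.42, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.999). The position of either probe set relative to the deleted part of the gene is not given, so Trib1 levels do not check the labels. Every genotype direction given here rests on the labels, and the arrays are called knockout-labelled.

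LPS treatment of wild-type macrophages was accompanied by large rises of inflammatory cytokine genes. Il6 went from a scaled intensity of 59.0 in medium to 17318 after LPS (294-fold), Il12b from 109.8 to 18743 (171-fold) and Il1b from 306.1 to 21197 (69.3-fold). Nos2, the inducible nitric oxide synthase, went from 42.6 to 7251 (170-fold), and Edn1, which encodes a vasoconstrictor peptide, from 41.4 to 6243 (151-fold). Cxcl3, a neutrophil chemoattractant, was under the floor in medium and reached 8309, at least 278-fold higher. The rest of the 10 largest rises were Il1a (48.1-fold), Il12a (39.7-fold), Cxcl1 (31.3-fold) and Ifng (at least 30.2-fold). The largest falls were in Rab7b, a small GTPase of late endosomes, from 1720 to 102.1 (16.8-fold lower), Tfeb, a regulator of lysosomal genes, from 847.5 to 73.2 (11.6-fold), Inpp5j (10.8-fold), Snx24 (9.82-fold) and Cd300lb (9.45-fold). All 10 rises, and the falls of Rab7b and Snx24, also reached 4-fold on both wild-type Trib1-line arrays. Tfeb (220.9 and 155.7 there) and Cd300lb (363.0 and 543.6, medium 1469) did not on both, and Inpp5j (292.3 and 991.3, medium 579.8) lay above medium on 1 of them.

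By the rule of at least 4-fold, 287 probe sets (166 genes) were induced and 174 (92 genes) repressed. The comparison has 1 array per condition, so no test or error applies. Of the induced probe sets, 128 (44.6%) were also at least 4-fold above medium on both wild-type Trib1-line arrays, and of the repressed, 65 (37.4%) were also at least 4-fold below it. Arrays of the same genotype and treatment also differed by 4-fold: 223 probe sets between the wild-type Trib1-line arrays and 212 between the knockout-labelled arrays, beside 461 for LPS. In simulated arrays with a spread fitted to the 4 Trib1-line arrays, 737 of 44837 unchanged probe sets passed the same rule. This also exceeds the 223 and 212 between like arrays, so the simulated spread was too large to set a background for the 461. Limma of the medium array against all 3 wild-type LPS arrays gave 45 higher and 3 lower of 28430 tested (Benjamini-Hochberg adjusted p under 0.05). Its spread comes from the LPS arrays alone, with the lone medium array assumed to vary like them, and 2 of those arrays belong to the Trib1 line. The median log2 ratio of LPS over medium, over probe sets above the floor on either array, was -0.09, and -0.10 with the values as deposited.

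Cytokine and chemokine genes made up the most responsive list: 17 of 26 members above the floor were induced, with a median log2 ratio of 2.44. Among genes of the NF-kB pathway and its feedback, 4 of 25 were induced (median 1.04): Traf1 (12.5-fold), Tnip1 (6.70-fold), Nfkbiz (6.60-fold) and Nfkb2 (5.22-fold). Of 32 interferon-stimulated genes, 10 were induced (median 0.63), among them the antiviral genes Mx2 (at least 10.5-fold), Mx1 (8.18-fold), Rsad2 (8.05-fold) and Cmpk2 (6.35-fold). This list already stood high in medium, with 24 of 32 genes above the 90th percentile of that array, so its ratios start from a high baseline. The C/EBP target list had 5 of 13 members induced (median 0.80): Il6, Csf3 (4.65-fold), Serpinb2 (16.9-fold), Lcn2 (11.2-fold) and Ptges (10.7-fold). Genes of nitric oxide and the oxidative burst had 3 of 16 induced (median 0.45), including the amino acid transporters Slc7a11 (16.4-fold) and Slc7a2 (13.3-fold). Among proteases and inhibitors 5 of 23 were induced and 1 repressed (median 0.35), with Timp1 16.5-fold and Mmp13 7.74-fold higher and Plau 9.06-fold lower. On both wild-type Trib1-line arrays Serpinb2 (326.6 and 569.9, medium 595.3) and Mmp13 (541.6 and 753.2, medium 1104) lay under medium, and Timp1 measured 1504 and 3222 (medium 1016). Csf3, Lcn2, Tnip1, Nfkbiz, Nfkb2 and Plau missed 4-fold on 1 or both of them. The costimulatory genes Cd80 (6.08-fold) and Cd40 (4.30-fold) were the induced members among 18 antigen presentation genes (median 0.33), with Cd40 missing 4-fold on wild type 1 of the Trib1 line.

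The prostaglandin gene Ptgs2 rose 13.6-fold and the prostaglandin receptor gene Ptger2 was 6.0-fold lower within the eicosanoid list, where 2 of 19 were induced and 1 repressed (median -0.27). Of 19 alternative activation genes, Ccl22 was induced (6.59-fold) and 2 were repressed, among them Pparg (at least 4.82-fold), with a median of -0.01. The Tribbles family and partners had 0 of 17 induced and 2 repressed (median -0.47), Cebpa 7.51-fold and Fos 6.87-fold lower, with Fos missing 4-fold on wild type 1 of the Trib1 line. In the glycolysis and hypoxia list 1 of 20 was repressed (median -0.12). No member met the 4-fold rule among 23 cell cycle genes (median -0.54), 24 sterol and lipid genes (-0.27), 21 TLR receptors and adaptors (0.31) or 24 macrophage identity genes (0.12).

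Among markers of other cell types, 1 of 11 neutrophil markers was induced (median 0.65), 2 of 15 T and NK cell markers (0.33; Gzmb at least 6.22-fold, Gzma 4.20-fold) and 1 of 10 dendritic cell markers (0.41; Ccr7 5.47-fold), with Gzmb, Gzma and Ccr7 missing 4-fold on wild type 1 of the Trib1 line. None met the rule among 11 eosinophil and mast cell markers (0.30), 13 B cell markers (0.39), 13 mesothelial and stromal markers (-0.01) or 2 sex-linked genes (-0.12). Against 10000 random lists of equal size and level, the medians of the cytokine, NF-kB and interferon lists stood at the 100th percentile, and C/EBP targets and neutrophil markers at 99.96. Lists with 0 induced members stood high too: B cell markers at 99.81, TLR genes at 99.8 and eosinophil and mast cell markers at 98.96. A high percentile is therefore not particular to LPS-induced lists. Macrophage identity genes (71.3) and mesothelial and stromal markers (71.2) stood lower. Cell cycle genes stood at percentile 0.38 and the Tribbles list at 0.60. Genes in a list are not independent replicates, and the percentiles describe this 1 pair of arrays.

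**Figure D1:**
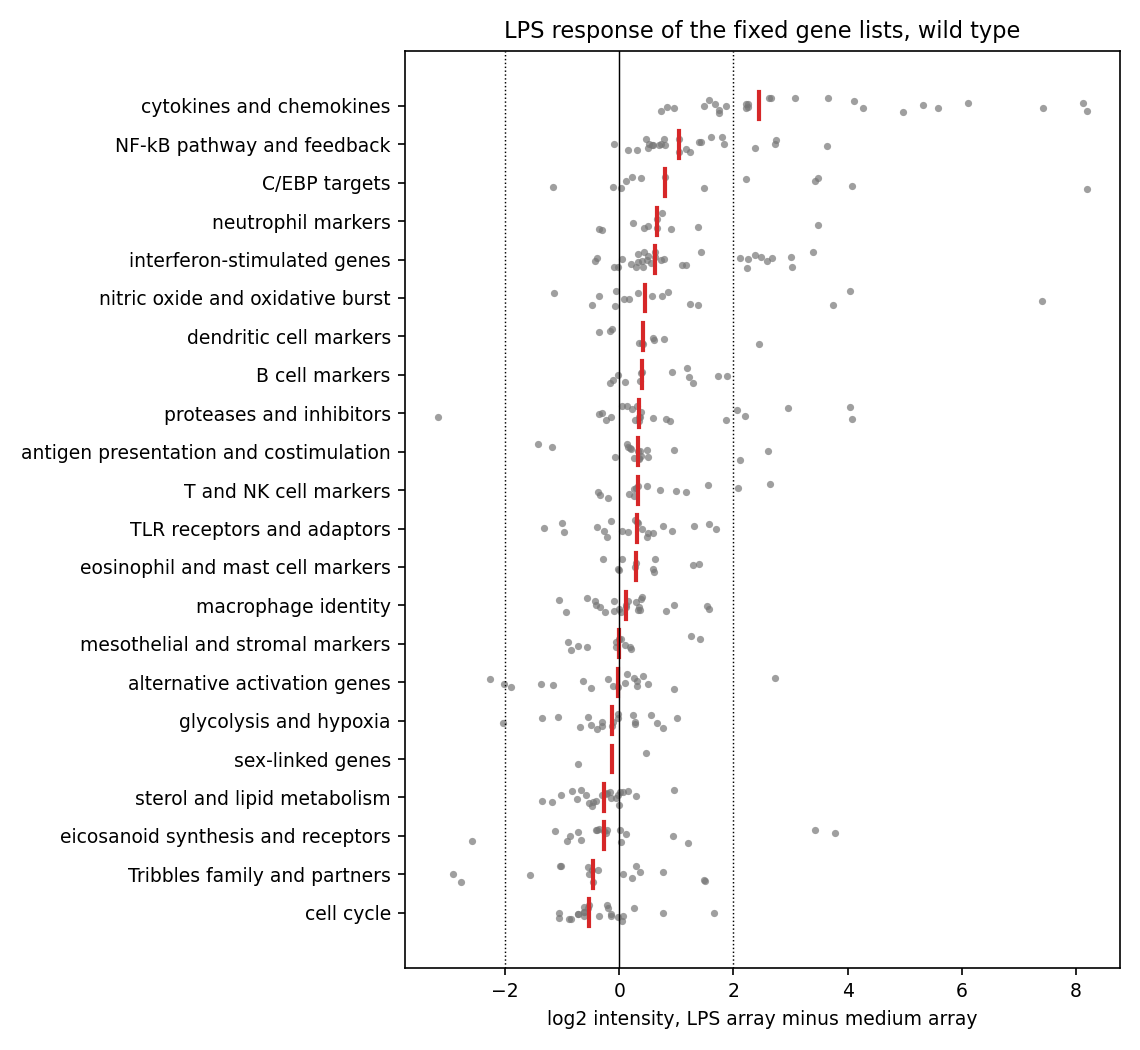
Log2 ratio of LPS over medium in the LPS pair for each fixed list, with 1 grey point per gene above the floor on either array, a red bar at the median and dotted lines at 4-fold. The median was 2.44 for cytokines and chemokines and -0.54 for cell cycle genes.

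Between genotypes, the genes with the smallest p included S100a8, which encodes a neutrophil and macrophage calcium-binding protein. Its scaled intensity was 1251 and 1238 on the wild-type arrays and 8853 and 7314 on the knockout-labelled arrays (6.47-fold, log2 2.69, SE 0.17, n = 2 per genotype; limma, Benjamini-Hochberg adjusted p = 0.216). Klrk1, an activating receptor of NK cells, measured 1671 and 1485 on wild-type arrays and 230.3 and 263.3 on knockout-labelled ones (log2 -2.68, SE 0.20, adjusted p = 0.216). Axl, a receptor tyrosine kinase for apoptotic cell uptake, measured 3706 and 3776 against 743.9 and 941.2 (log2 -2.16, SE 0.19, adjusted p = 0.281). Tlr2, a receptor for bacterial lipopeptides, measured 843.8 and 1058 against 3170 and 3135 (log2 1.74, SE 0.19, adjusted p = 0.579). None of these passed the test over all probe sets.

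Over all 29078 probe sets tested (13897 genes), limma called 0 higher and 0 lower on the knockout-labelled arrays at a Benjamini-Hochberg adjusted p under 0.05. Both directions had calls when the number of the labels was taken as a block, as given below with the limits of that fit. At an unadjusted p under 0.05 in the fit without the block, 663 were higher and 788 lower, a sum of 1451, with 1454 given by chance. The block raised that sum, as given below. Leaving out 1 array made calls: 5 higher and 0 lower without wild type 1, 19 and 9 without knockout 1, 12 and 0 without wild type 2, and 36 and 32 without knockout 2. The remaining genes that led by p with log2 differences above 0 were Wfdc21 (4.10, adjusted p = 0.216), Rusc1 (3.34, adjusted p = 0.287), Emp1 (2.16), Ptges (1.67), Stab1 (2.26), Rps4l (at least 6.96-fold), Ereg (2.80) and Dusp6 (1.72), the last 6 with an adjusted p = 0.766. Other probe sets of Rusc1 ran from -0.22 to 0.55. Those with log2 differences under 0 were Sgcb (-1.61), Cap1 (-2.36), Nectin2 (-1.56), Tspan33 (-2.27), Ryk (at least 4.16-fold), G530011O06Rik (-2.75), Snn (-2.22) and Lrrc27 (at least 3.64-fold), with adjusted p of 0.766 or 0.782. On the LPS array of the LPS pair, also wild type, Rusc1 (813.6), Emp1 (7611) and Tlr2 (5282) reached or passed the knockout-labelled values, and Cap1 (225.2), Nectin2 (190.5) and Tspan33 (56.1) lay under the higher knockout-labelled value.

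By a rule of size, 113 probe sets (68 genes) had both knockout-labelled arrays at least 2-fold above both wild-type arrays, and 96 (46 genes) at least 2-fold below. The same rule gave 401 for the arrays numbered 1 against those numbered 2, and 81 for the third split. Among LPS-induced probe sets the genotype split gave 16 higher and 5 lower, beside 8 and 1 in all for the other splits. In 33 of the 113 and 26 of the 96, the wild-type LPS array of the LPS pair reached the knockout-labelled level.

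The series asks which LPS-inducible genes differ with Trib1. Csf3, which encodes the granulocyte growth factor, rose from 129.8 and 285.8 on the wild-type arrays to 1092 and 1316 on the knockout-labelled arrays (6.22-fold, log2 2.64, SE 0.40). Ptges, which encodes the inducible prostaglandin E synthase, rose from 1693 and 2396 to 5922 and 6979 (3.19-fold, log2 1.67, SE 0.23). Gja1, a gap junction protein gene, rose from 148.6 and 84.2 to 479.9 and 576.5 (4.70-fold, log2 2.23, SE 0.35). In medium Csf3 measured 37.6, Ptges 204.5 and Gja1 157.0, so Gja1 lay under medium on both wild-type Trib1-line arrays and counts as LPS-induced by the LPS pair alone (676.4). Each had n = 2 per genotype and an adjusted p = 0.0362 by limma, with Benjamini-Hochberg adjusted over the list alone.

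Of 281 LPS-induced probe sets tested, 9 were higher and 0 lower on the knockout-labelled arrays, adjusted over the list alone, and 0 adjusted over all probe sets (limma). The 9 and 0 are for the fit without a block. Taking the number of the labels as a block gave more calls in both directions, as given below. Without the block the 9 were 4 probe sets of Gja1, 2 of Ptges, 1 of Csf3, 1 of Acpp and 1 without a gene name. The most highly expressed probe set of Acpp, a phosphatase gene chosen for mention after its values were seen, did not pass (adjusted p = 0.107). At an unadjusted p under 0.05 there were 42 higher and 28 lower, with 14.1 given by chance for both directions. Leaving out wild type 1, knockout 1, wild type 2 or knockout 2 gave 15, 20, 30 or 36 higher and 12, 12, 1 or 42 lower. With the LPS array of the LPS pair as an added wild type, 3 were higher and 1 lower, and 3 of the 9 passed, but the list was chosen for high values on that array, which by itself lowers these differences. That array also differed from the Trib1-line arrays in deposited scale and, by Xist and Eif2s3y, in sex, as given below. A call lost with it, here or below, can come from that difference. Without the filter on low values 0 passed (the 9 reached an adjusted p of 0.0774), and without a trend in the prior 1 passed.

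Among LPS-induced genes short of the threshold, the smallest p with log2 differences above 0 belonged to Serpinb2 (2.19, adjusted p = 0.0533 by limma and Benjamini-Hochberg over the list alone), Rpusd3 (1.58, 0.0645), Il1f6 (1.49, 0.0816), Phlda1 (1.79, 0.0816), U90926 (2.77, 0.0836), AA467197 (1.10, 0.0836) and Calcrl (1.49, 0.0851). With log2 differences under 0 they were Ly6d (at least 3.13-fold, 0.0570), Armcx6 (-2.48, 0.0645), A630072M18Rik (-1.14, 0.0816), Thbs4 (-1.98, 0.0959), Ltb (-1.55, 0.107), Tgfb1i1 (-1.32, 0.112), Ms4a4b (-1.31, 0.120), Ccl22 (-1.08, 0.131), Gzma (-1.35, 0.180) and Ifng (-1.21, 0.276). As sets, neither the 163 LPS-induced genes (76 above and 87 below 0; 0.843) nor the 83 LPS-repressed genes (0.271) passed camera with the preset correlation (unadjusted values in parentheses).

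Differences between knockout 1 and wild type 1 and between knockout 2 and wild type 2 share no array. Over the 281 LPS-induced probe sets they correlated with Pearson r = 0.58 and Spearman rho = 0.58, and 201 (71.5%) had the same sign. Crossed pairs gave r = 0.04 and rho = 0.15. Over all 29078 probe sets r was 0.20 and rho 0.18, against -0.16 and -0.19 for the crossed pairs. The labels do not say that the numbers pair arrays, and probe sets are not independent replicates, so no p is given for these 4 relations.

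**Figure D2:**
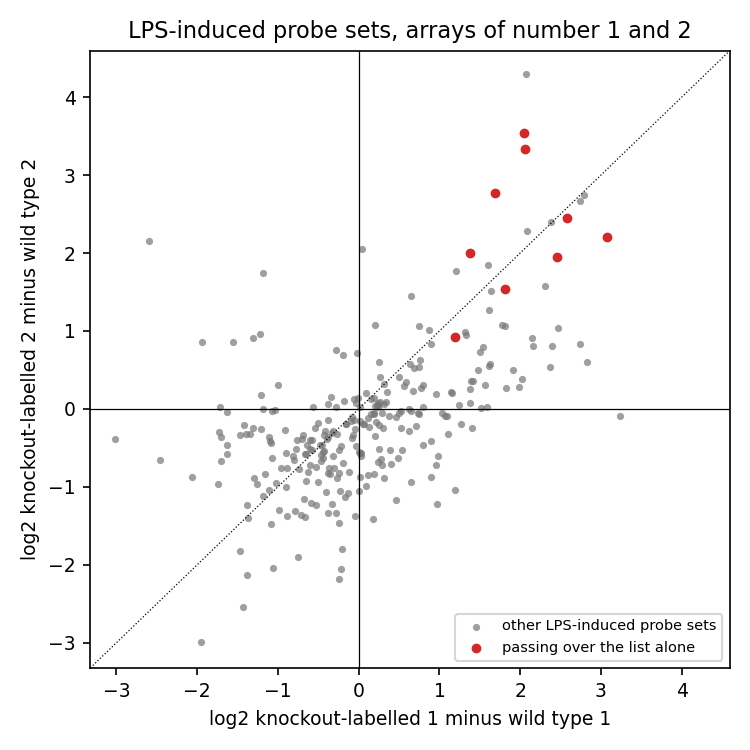
Log2 difference of knockout 1 over wild type 1 (x axis) and of knockout 2 over wild type 2 (y axis) for 281 LPS-induced probe sets, 1 point each. The 9 in red passed adjusted over the list alone and lie above 0 on both axes.

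Among C/EBP target genes, transcripts driven by the factors that Trib1 helps to degrade, 5 rose. Hp, which encodes the haemoglobin scavenger haptoglobin, rose from 131.1 and 249.7 on wild-type arrays to 859.5 and 1054 on knockout-labelled arrays (5.26-fold, log2 2.39, SE 0.35; limma adjusted p = 0.00313, Benjamini-Hochberg over the list alone). Ptges and Csf3 rose with the same adjusted p over this list. Serpinb2, a serine protease inhibitor gene, rose from 326.6 and 569.9 to 1391 and 2771 (4.55-fold, log2 2.19, SE 0.42, adjusted p = 0.0074). Lcn2, whose product binds bacterial siderophores, rose from 3714 and 394.6 to 15576 and 7749 (9.07-fold, log2 3.18, SE 1.0, adjusted p = 0.0474).

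In all, 5 of the 13 members rose and 1 fell, Il10ra, an interleukin receptor gene (log2 -0.67, SE 0.20, adjusted p = 0.0455 over the list alone, limma and Benjamini-Hochberg). Another probe set of Il10ra had a log2 difference of 1.06 (SE 0.61), with wild type 2 under the floor (5.0) and wild type 1 at 91.3. Ptges, Lcn2, Arg1 and Serpinb2 are remembered from the study itself, so they are not independent evidence of the list's direction. Arg1, encoding arginase, measured 1135 and 250.1 against 4767 and 1626 (log2 2.39, SE 0.81) and did not pass (adjusted p = 0.0515). Msr1 (log2 0.77, adjusted p = 0.133), Cebpb (0.45, 0.231), Saa3 (0.21, 0.423), Il6 (0.14, 0.755), Cebpd (0.12, 0.760) and Il13ra1 (0.11, 0.755) did not pass. The list's median was 0.77, with 12 of 13 means above 0 under all 3 scalings. Camera with a preset correlation of 0.01 gave an adjusted p = 2.90e-06 over the 22 lists, and an adjusted p = 0.398 (0.0306 unadjusted) with an estimated correlation. The adjustment gave several lists this 0.398. The list's estimated correlation was -0.062, under the preset value, so correlation among its genes does not account for the change. With an estimated correlation camera uses the 2 residual degrees of freedom, which by itself raises the p-value. Without the 4 remembered genes, an alternative chosen after the data were seen, the median of the other 9 was 0.21 and the adjusted p = 0.00552, or 0.398 with an estimated correlation.

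Single arrays weighed on several of these values. Without wild type 2 the median of the C/EBP list was 1.29. Lcn2 had a log2 difference of 4.80 without wild type 1 and 1.56 without wild type 2, and its adjusted p over the alternatives ran from 6.20e-05 to 0.0910. Il10ra lost its call without wild type 1 (adjusted p = 0.171 over the list alone, limma), wild type 2 (0.0522) or knockout 2 (0.172). With the LPS array of the LPS pair, where Serpinb2 measured 10077, as an added wild type, the log2 difference of Serpinb2 was 0.67 (adjusted p = 0.802). Ptges, Hp and Csf3 passed in all 13 alternatives.

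**Figure D3:**
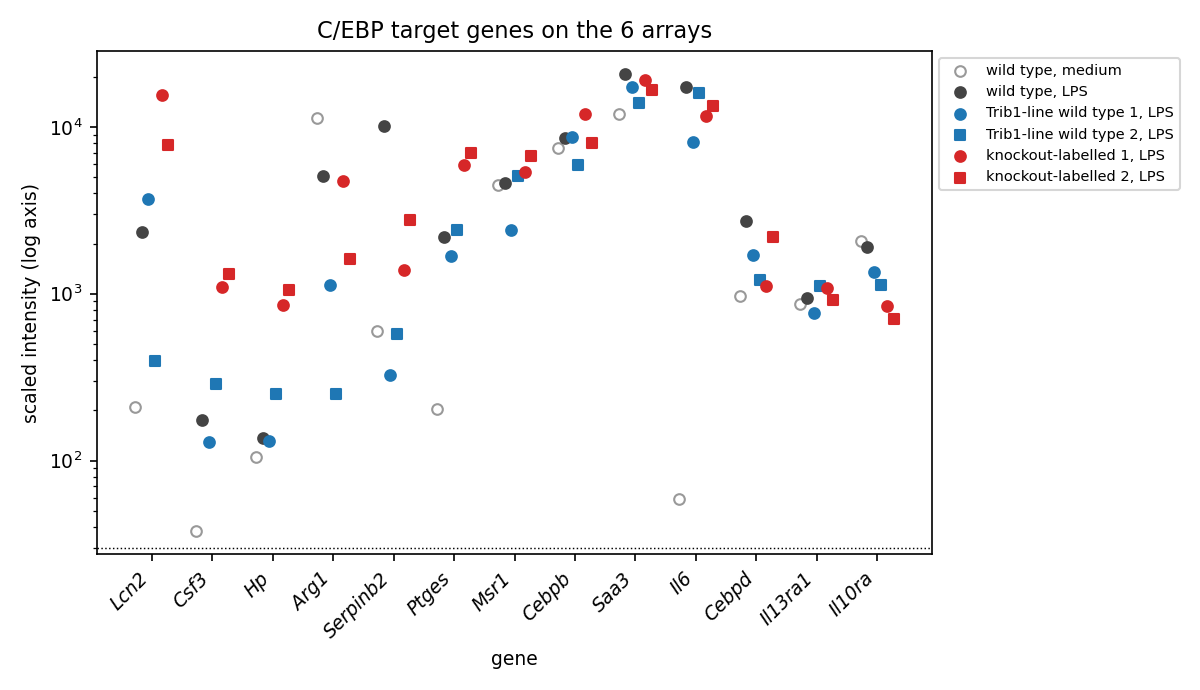
Scaled intensity (log axis) of the 13 C/EBP target genes, 1 point for each of the 6 arrays, with a dotted line at the floor of 29.9. Hp measured 131.1 and 249.7 on wild-type and 859.5 and 1054 on knockout-labelled arrays.

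Beside the C/EBP targets, 5 of 13 neutrophil markers rose and 1 fell, adjusted over the list alone. S100a8 rose 6.47-fold (limma adjusted p = 9.71e-05, Benjamini-Hochberg over the list alone). S100a9, its binding partner, was under the floor on both wild-type arrays and measured 6906 on knockout 1 and 205.6 on knockout 2, at least 39.9-fold higher (adjusted p = 0.0442). Mmp8, a neutrophil collagenase gene, rose from 212.1 and 121.8 to 2587 and 713.6 (8.45-fold, log2 3.08, adjusted p = 0.0211). Camp, an antimicrobial peptide gene, rose from under the floor to 219.9 and 66.9 (adjusted p = 0.0442). Ltf, which encodes lactoferrin of neutrophil granules, fell by a log2 difference of 1.33, from 87.0 and 87.2 to 40.2 and 12.7 (adjusted p = 0.0389). Lcn2 is in both lists. The median was 0.46, with 11 of 13 above 0 (camera adjusted p = 0.000144, and adjusted p = 0.398 with an estimated correlation).

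The log2 difference of Mmp8 was 2.15 without knockout 1 and 4.01 without knockout 2, and the median of the neutrophil list was 0.95 without wild type 2. Ltf lost its call without wild type 2 (adjusted p = 0.0544, limma, over the list alone), without knockout 2 (0.134) and with the added wild type (0.318), and Camp without wild type 2 (0.0544). S100a9 and Camp were not tested without either knockout-labelled array, since 1 array above the floor remained. With the floor at the 25th percentile the log2 differences of S100a9 and Camp were 6.45 and 3.16, and with it at the 60th those of S100a9 and Ltf were 4.08 and -0.30.

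Protease and inhibitor genes included 5 that rose and 1 that fell of 23, adjusted over the list alone. Besides Serpinb2 and Mmp8 these were F13a1, a coagulation factor subunit gene (158.0 and 141.5 to 657.2 and 430.6, log2 1.83), Mmp9, a gelatinase gene (log2 1.72), and Slpi, a leukocyte protease inhibitor gene (1.02). Timp2, a metalloprotease inhibitor gene, fell (log2 -0.76). All had an adjusted p = 0.0228 by limma and Benjamini-Hochberg except Slpi (0.0234). The median was 0.13, with 13 of 23 above 0 (camera adjusted p = 0.00501, and adjusted p = 0.398 with an estimated correlation). That call was lost without wild type 1 (adjusted p = 0.0677) and with the added wild type (median 0.09, 0.529). The median was 0.36 without knockout 1, 0.38 without wild type 2 and 0.20 with the values as deposited.

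Calls of single genes depended on arrays here too. F13a1 measured 1373 on the LPS array of the LPS pair and had an adjusted p = 0.742 (limma, over the list alone) with it as an added wild type. That array differed from the Trib1-line arrays in deposited scale and sex, so calls lost with it do not gauge the genotype difference alone. Slpi lost its call without wild type 1 (0.0794) and with the added wild type (0.223). Mmp9 lost it without knockout 1 (0.0535) or wild type 2 (0.0503). Timp2 lost it without wild type 1 (0.0794), wild type 2 (0.0503) or knockout 2 (0.0537), and with the added wild type (0.148).

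Among 26 cytokines and chemokines, Csf3 (limma adjusted p = 0.0188, Benjamini-Hochberg over the list alone) and Il23a, an interleukin subunit gene, rose (73.7 and 129.4 to 433.9 and 272.1, log2 1.81, 3.52-fold, 0.0459). Il12b, whose product pairs with that of Il23a, fell (15341 and 14355 to 8829 and 9118, log2 -0.73, 0.0459). The median was 0.36, with 19 of 26 above 0 (camera adjusted p = 0.00145, and adjusted p = 0.497 with an estimated correlation). Without wild type 1 the list's median was -0.02 and the adjusted p = 0.663, without wild type 2 the median was 0.72, and with the added wild type it was 0.21 and the adjusted p = 0.221. Il23a and Il12b lost their calls without wild type 1 (0.126 and 0.166), without knockout 1 (0.0816 each) and with the added wild type (0.0507 each).

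In the eicosanoid list, Ptges (limma adjusted p = 0.00548, Benjamini-Hochberg over the list alone) and Ptger2, a prostaglandin E receptor gene, rose (31.1 and 36.2 to 166.5 and 184.3, log2 2.38, 5.22-fold, 0.00548), with both wild-type values just above the floor and a log2 difference of 1.31 with the floor at the 60th percentile. Tbxas1, the thromboxane synthase gene, fell (log2 -1.04, 0.0142), without a call when wild type 1 (0.0788) or knockout 2 (0.0735) was left out. The median of its 18 members was 0.27, with 10 above 0 (camera adjusted p = 0.139, and adjusted p = 0.472 with an estimated correlation), and it was -0.061 with the added wild type. Of 17 genes of nitric oxide and the oxidative burst, Arg2, the mitochondrial arginase gene, rose (559.9 and 211.9 to 2807 and 2055, log2 2.80, 6.97-fold, 0.0103). So did Hmox1, the inducible haem oxygenase gene (log2 1.03, 2.05-fold, 0.0103). The log2 difference of Arg2 was 3.50 without wild type 1 and 2.10 without wild type 2. The list's median was 0.09, with 12 of 17 above 0 (13 with the values as deposited; camera adjusted p = 0.00533, and adjusted p = 0.398 with an estimated correlation). It did not pass without wild type 1 (median 0.056, 0.0613), and its median was 0.18 without wild type 2 and 0.16 with the values as deposited.

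In the NF-kB list, Irak3, a brake on Toll-like receptor signalling (log2 1.23), and Ier3, an early response gene (0.85), rose (limma adjusted p = 0.0395 for both, Benjamini-Hochberg over the list alone). Irak3 lost its call without wild type 2 (0.123), and Ier3 without wild type 1 (0.110), knockout 1 (0.0956) or wild type 2 (0.153). The median of 25 members was 0.07, with 17 above 0 (19 with the values as deposited, 16 after quantile normalization; camera adjusted p = 0.139, and adjusted p = 0.539 with an estimated correlation). Without knockout 2 the list passed (median 0.13, adjusted p = 0.0165), and with the added wild type its median was -0.12. It was 0.015 without knockout 1, 0.16 without wild type 2 and 0.14 with the values as deposited. Among 21 TLR receptors and adaptors Tlr2 rose (0.00251), without a call when the added wild type was added (0.658). That list's median was -0.01, with 10 above 0 (12 with the values as deposited, 9 after quantile normalization; camera adjusted p = 0.895, and adjusted p = 0.933 with an estimated correlation), and camera and fry gave it opposite directions. It was 0.012, 0.021 and 0.036 without wild type 1, knockout 1 and wild type 2, and 0.054 with the values as deposited, but -0.16 without knockout 2, -0.041 after quantile normalization and -0.23 with the added wild type.

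Interferon-stimulated genes had lower means on the knockout-labelled arrays in 32 of 32 members, under all 3 scalings, with a median of -0.46. Those with the smallest p were Stat2 (log2 -0.53) and Irf8 (-0.39), transcription factors of interferon signalling. No member passed (limma, both 0.521 adjusted over the list alone by Benjamini-Hochberg). Camera gave an adjusted p = 3.20e-06, and an adjusted p = 0.496 with an estimated correlation. Without knockout 1 the median was -0.07 and the adjusted p = 0.445, and the medians were -0.64, -0.18 and -0.77 without wild type 1, wild type 2 and knockout 2. Within genotypes the list's median difference was -0.59 for wild type 1 minus wild type 2 and -0.96 for knockout 1 minus knockout 2.

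Antigen presentation and costimulation genes had means under 0 in 18 of 18 members, but 4 (Tap2, B2m, H2-K1 and H2-D1) were above 0 with the values as deposited. The median was -0.21. H2-DMa (log2 -0.62, adjusted p = 0.183) and Cd80 (-0.89, 0.258) had the smallest p, and none passed (limma, Benjamini-Hochberg, adjusted over the list alone). Camera gave an adjusted p = 6.02e-05, and an adjusted p = 0.398 with an estimated correlation. The 17 alternative activation genes had a median of -0.21, with 8 above 0, and none passed (Arg1 and Ccl22, 0.197). Camera gave an adjusted p = 0.467 for that list, 0.570 with an estimated correlation, and 0.0377 with the added wild type (median -0.38). Its median was -0.068, -0.032, -0.028 and 0.0022 without wild type 1, knockout 1, wild type 2 and knockout 2, and -0.094 with the floor at the 25th percentile.

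**Figure D4:**
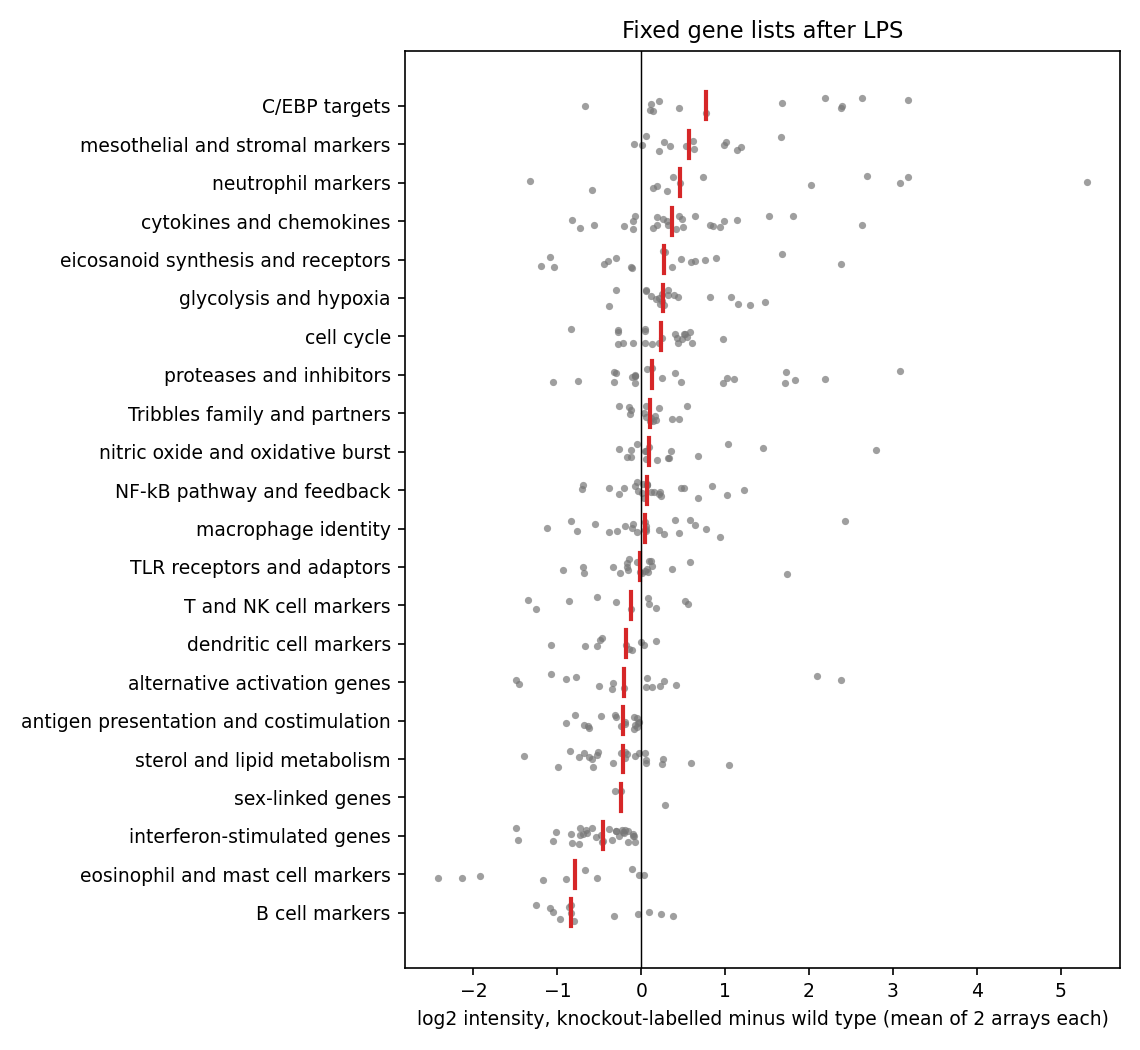
Log2 difference of knockout-labelled over wild-type arrays for each fixed list, with 1 grey point per tested gene and a red bar at the median. The median was 0.77 for C/EBP targets and -0.46 for interferon-stimulated genes.

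On the knockout-labelled arrays 4 mast cell markers fell. Cma1, a chymase gene, went from 175.4 and 286.6 to 11.5 and 58.3 (log2 -2.43, 5.37-fold lower) and Tpsb2, a tryptase gene, from 134.2 and 148.4 to 39.7 and 34.6 (log2 -1.93, 3.81-fold lower; limma adjusted p = 0.0146 for both, Benjamini-Hochberg over the list alone). Cpa3, the mast cell carboxypeptidase gene, went from 297.1 and 366.8 to 47.8 and 117.8 (log2 -2.14, 4.40-fold lower, 0.0181). Fcer1a, a subunit of the IgE receptor, was at least 2.26-fold lower (0.0216). Of all 10 eosinophil and mast cell markers tested, 9 had means under 0 (8 with the values as deposited, 7 after quantile normalization, where Kit or Prg2 and Kit turned). The median was -0.78, -0.50 without wild type 2 and -0.39 with the added wild type (camera adjusted p = 3.67e-06, and adjusted p = 0.398 with an estimated correlation). The log2 difference of Cpa3 was -1.49 without knockout 1 and -2.79 without knockout 2. With the floor at the 60th percentile that of Cma1 was -1.67 and that of Tpsb2 -1.001. Fcer1a lost its call without knockout 1 (0.105) or knockout 2 (0.111) and was not tested without either wild-type array.

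Mesothelial and stromal markers had 13 of 14 means above 0 (12 after quantile normalization, with Lum under 0) and a median of 0.57. Pdpn, which encodes podoplanin, rose from 6118 and 4849 to 12532 and 12270 (log2 1.19, 2.28-fold; limma adjusted p = 0.0114, Benjamini-Hochberg over the list alone), without a call when wild type 2 was left out (0.0590). Camera gave this list an adjusted p = 7.97e-05, and an adjusted p = 0.410 with an estimated correlation, and the median was 0.32 without knockout 2, 0.99 with the floor at the 60th percentile and 0.34 without the filter. B cell markers had 10 of 13 means under 0 (9 with the values as deposited) and a median of -0.83. None passed, with the smallest p for Pou2af1 (log2 -1.08) and Fcer2a (-1.06; both 0.164). The B cell list had a camera adjusted p = 0.000381, and an adjusted p = 0.496 with an estimated correlation. That call was lost without knockout 1 (median -0.51, adjusted p = 0.0592) or wild type 2 (-0.35, 0.139), and the median was -0.23 with the floor at the 60th percentile.

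Dendritic cell markers had a median of -0.19 with 3 of 11 above 0, and none passed (limma; Itgax log2 -1.07, adjusted p = 0.184 over the list alone; Siglech -0.68, 0.555). Their camera adjusted p was 0.0263, with an adjusted p = 0.398 with an estimated correlation. That call was lost without knockout 1 (median -0.43, adjusted p = 0.0514) or knockout 2 (-0.28, 0.119), after quantile normalization (0.0598) and with the added wild type (0.0594), and the median was -0.42 without wild type 1 and -0.35 without wild type 2. It was -0.35 with the floor at the 60th percentile and -0.12 with the values as deposited. T and NK cell markers had a median of -0.13 with 5 of 11 above 0 and none passing (Cd247 -1.26, limma adjusted p = 0.0780, and Il7r 0.52, 0.0983). Of 2 other probe sets of Cd247, 1 near the floor had 0.32 and 1 was at least 2.13-fold lower. For T and NK cell markers the camera adjusted p was 0.335, and 0.673 with an estimated correlation. Their median was -0.19 without wild type 1, 0.052 without wild type 2, -0.37 without knockout 2, -0.40 with the added wild type, -0.67 with the floor at the 60th percentile and -0.023 with the values as deposited. Macrophage identity genes had a median of 0.05 with 14 of 24 above 0 (15 under both other scalings), and none passed (Itgam 0.64 and Fcgr2b 2.42, both 0.0857; camera adjusted p = 0.467, and 0.673 with an estimated correlation). Their median was -0.0075 without knockout 1, 0.027 without wild type 2, -0.042 with the added wild type and 0.12 with the values as deposited. Sex-linked genes had a median of -0.24 over 3 members, and none passed (Kdm5d -0.32, another probe set 0.16; Uty -0.24; both 0.554; camera adjusted p = 0.643, and 0.692 with an estimated correlation), with a median of -0.020 without wild type 1, -0.36 without wild type 2, -0.095 without knockout 2 and 0.40 with the added wild type.

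Glycolysis and hypoxia genes had means above 0 in 18 of 20 members (median 0.26), with the smallest p for Egln3, an oxygen sensor gene (log2 1.16), and Pfkfb3, a regulator of glycolysis (1.30), neither passing (limma, 0.431 adjusted over the list alone by Benjamini-Hochberg). By camera the list had an adjusted p = 0.00501, and an adjusted p = 0.507 with an estimated correlation. The call was lost without wild type 1 (0.0613) or knockout 1 (median -0.0028, 0.966), and the median was 0.60 without knockout 2. Sterol and lipid genes had 17 of 24 means under 0 (16 with the values as deposited) and a median of -0.22. Fdps (-0.998) and Insig1 (-0.63), genes of sterol synthesis and its feedback, did not pass (0.243). Camera gave the sterol list an adjusted p = 0.00646, and an adjusted p = 0.398 with an estimated correlation. That call was lost without wild type 1 (0.0613) or knockout 2 (median -0.09, 0.202), and the median was -0.34 without wild type 1, -0.37 without wild type 2 and -0.35 with the added wild type.

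Cell cycle genes had a median of 0.23 with 16 of 22 above 0, and none passed (limma; Birc5 0.98 and Mcm6 -0.84, both 0.598 adjusted over the list alone). Their median was 0.41 without knockout 1, 0.086 with the floor at the 25th percentile and 0.13 without the filter. Their camera adjusted p = 0.0708 became an adjusted p = 0.496 with an estimated correlation. The Tribbles family and partners had a median of 0.11 with 12 of 16 above 0, and none passed. The smallest p belonged to Mapk14 (0.54) and Cop1, the ubiquitin ligase that binds Tribbles proteins (-0.26), both 0.854 adjusted over the list alone. Other probe sets of Mapk14 had log2 differences of 1.005, 0.49, 0.42, -0.11 and -0.57, with those of 0.49 and -0.11 near the floor. The camera adjusted p of the Tribbles list was 0.346, and 0.507 with an estimated correlation. That list's median was 0.29, 0.019, -0.13 and 0.33 without wild type 1, knockout 1, wild type 2 and knockout 2, 0.042 with the added wild type and 0.175 with the values as deposited.

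Across the 22 lists, camera with the preset correlation passed 13 (Benjamini-Hochberg over the lists). With an estimated correlation 0 passed (smallest adjusted p = 0.398, which the adjustment gave to several lists alike). That form of camera uses the 2 residual degrees of freedom, so a list needs a far larger shift to pass. Failing it is thus weak evidence against a list. Fry, which tests whether a list's genes move on balance one way, also passed 0 (smallest adjusted p = 0.202). Calls of genes over a list alone were adjusted within each list and not across the 22 lists. The alternatives keep that adjustment, and in the main fit no gene passed over all probe sets. Of 29 genes that passed over a list alone, 9 passed in all 13 alternatives: Ptges, Csf3, Hp, S100a8, Mmp8, Ptger2, Cma1, Cpa3 and Tpsb2.

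Genes around Trib1 were examined because sequence near a targeted locus can come from another strain. Of the 150 genes on each side, 69 were tested and 4 (5.80%) had an unadjusted p under 0.05, against 765 of 13828 others (5.53%; Fisher's exact test, two-sided p = 0.792). Ext1 and Sla had log2 differences of 0.79 and 1.04, and Wdyhv1 and Atad2 of -0.74 and -1.30. As a set they did not pass camera (unadjusted value 0.932), and 0 passed over all genes (limma, Benjamini-Hochberg). Across all tested probe sets the LPS response and the genotype difference, which share no array, correlated with r = -0.03 and rho = -0.06.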

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

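The alternative scalings and floors for the 2 correlations and for the neighbours of Trib1, and the C/EBP list without 4 genes, were chosen only after the results were seen; the other alternatives were planned. Unless a cause is given, the cause was not tested.

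Counts for LPS against medium (287 induced, 174 repressed) depended on the floor and the fold rule by construction, since a lower floor lets weak signals vary. They were 501 and 465 with the floor at the 25th percentile and 85 repressed with it at the 60th. A 2-fold rule gave 1461 and 1832, and an 8-fold rule 82 and 17. Wild type 1 in place of the LPS array gave 370 repressed, and wild type 2 gave 447 and 489. Limma with 3 wild-type LPS arrays gave 45 and 3.

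Of the 281 LPS-induced probe sets, 9 higher and 0 lower became 14 and 3 with the values as deposited, and 14 and 3 with log2 of the value plus 16. Quantile normalization gave 1 lower. No filter gave 0 higher, the added wild type 3 and 1, and a prior without a trend 1 higher. The list by a 2-fold rule, which adjusts over more probe sets, gave 0 higher, and that by an 8-fold rule 1 lower. Leaving out 1 array gave from 15 to 36 higher and from 1 to 42 lower, with the lone array assumed to vary like the other genotype. Over all probe sets this gave from 5 to 36 higher and from 0 to 32 lower.

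With the number of the labels as a block, 53 LPS-induced probe sets were higher and 78 lower, and 85 and 31 over all probe sets. Deviations from the group means of the arrays that share a number correlated with r = 0.35 across probe sets, so the block removes a shared part. The block leaves 1 residual degree of freedom, with a prior of 5.70 against 3.68 without it. At an unadjusted p under 0.05 (limma) it gave 3261 of all probe sets, against 1451 without it. The labels say only that arrays share a number, so these counts rest on a pairing that the labels do not state.

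The 2-fold separation of the genotypes (113 higher, 96 lower) became 288 and 303 with the floor at the 25th percentile and 68 and 35 with it at the 60th. The correlation of the numbered differences (0.20) was 0.11 and 0.34 with these floors and 0.17 with log2 of the value plus 16. That of the LPS response with the genotype difference (-0.03) was -0.020 and -0.055 with the 25th and 60th percentiles. Of 22 lists, 13 passed camera, from 8 to 12 with 1 array left out, and 0 with an estimated correlation or fry.

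Some values near 0 changed sign. The TLR list had a median of 0.054 with the values as deposited and from -0.16 to 0.036 with 1 array left out, while fry gave the direction opposite to its median of -0.014. With 1 array left out the Tribbles list ran from -0.13 to 0.33 and the sex-linked list, whose test changed direction, from -0.36 to -0.020. With the added wild type the sex-linked list had 0.40, the NF-kB list -0.12, the macrophage identity list -0.042, Il6 -0.067, Cebpd -0.19 and Uty 0.40. For Uty, a Y-linked gene, this follows from the added array, which measured 4.0, against 129.8 and 96.0 on the wild-type Trib1-line arrays. Medians that changed sign without a change in their test's direction were those of the alternative activation list without knockout 2 (0.0022), the T and NK cell list without wild type 2 (0.052), the macrophage identity list without knockout 1 (-0.0075), the cytokine list without wild type 1 (-0.019), the glycolysis list without knockout 1 (-0.0028) and the eicosanoid list with the added wild type (-0.061). With 1 array left out Il6 ran from -0.35 to 0.62, Il13ra1 from -0.16 to 0.38, Kdm5d from -0.67 to 0.036 and Cebpd from -0.38 to 0.61.

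In all, 65 values of main results stayed within the limits set and 53 moved. Of values of lists, 275 kept direction and side of the threshold, 42 lost a call, 2 gained one and 11 reversed. Of genes named between genotypes 1065 values kept both, 67 gained a call and 9 reversed. Of calls over a list alone, 362 were kept and 72 lost. Since no gene named between genotypes passed over all probe sets in the main fit, its values could lose no call. All 75 values of genes named for LPS stayed, under scalings and floors that use the same 2 arrays. With a wild-type Trib1-line array in place of the LPS array, Tfeb, Cd300lb and Inpp5j missed 4-fold on 1 or both, as given above. Signal over background limits genes near the floor: 52 induced probe sets were under it in medium and 50 repressed ones after LPS, so their folds are lower bounds, and S100a9 and Camp could not be fitted without either knockout-labelled array.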

Other observations

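All tests below were chosen only after the result was seen, except that of variation between arrays for the interferon-stimulated genes, and the genes outside the fixed lists were chosen after their values were seen. The 7 genes that follow had both knockout-labelled arrays at least 2-fold above both wild-type arrays, and none passed limma over all probe sets. Il1f9, a cytokine of the interleukin family, had scaled intensities of 138.8 and 531.5 on wild-type and 2594 and 1784 on knockout-labelled arrays. Trem1, an amplifying receptor of myeloid cells, measured 62.7 and 56.5 against 318.2 and 192.5, and Ltb4r1, a leukotriene receptor, 314.4 and 114.1 against 1002 and 668.7. Steap4, a metalloreductase gene, measured 60.9 and 29.0 against 441.9 and 231.0, Glrx, a glutaredoxin gene, 398.7 and 691.4 against 2240 and 3635, and Cd24a, a surface glycoprotein gene, 240.5 and 250.5 against 1204 and 734.8. Lox, the gene of a collagen crosslinking enzyme, measured 31.2 and 6.6 against 291.1 and 130.0.

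The wild-type arrays of the LPS pair differed from the wild-type Trib1-line arrays in several genes. In medium and LPS, Emp1 measured 7952 and 7611, Fcgr2b 7956 and 6000, F13a1 1613 and 1373, and Ltc4s 2308 and 1911. On the medium array 10 of 32 interferon-stimulated genes lay above the 99th percentile of all probe sets, and the list's median was at percentile 97.1. Gbp2 was highest (21238) and Mx2 lowest (percentile 24.0, under the floor). Xist, expressed from the inactive X chromosome, measured 1616 and 980.5 on the LPS pair and at most 5.6 on the Trib1-line arrays. Eif2s3y, a Y-linked gene, measured 0.3 and 4.7 on the LPS pair, 534.2 and 218.8 on wild type 1 and 2, and 471.7 and 366.6 on knockout 1 and 2.

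Of C/EBP targets and of neutrophil markers, 5 of 13 each passed higher on the knockout-labelled arrays and 1 each lower, adjusted over the list alone. Neither list passed camera with an estimated correlation, but with 2 residual degrees of freedom that is weak evidence against a shift. Cis effects of another strain's sequence near Trib1 are argued against for the 5 passing targets, since 0 of them lay among the neighbours of Trib1. The positions of these genes do not depend on the arrays, so this is no test of the data. Another strain's sequence elsewhere, and effects in trans, were not tested. Neutrophils in these samples stay open for the targets outside the neutrophil list (Ptges, Serpinb2, Csf3 and Hp): their median log2 ratio of knockout 1 over knockout 2 was -0.282, but those of the 5 markers ran from 0.28 for S100a8 to 5.07 for S100a9, so they gauge no single share of cells. For the markers they stay open too, since Csf3r, abundant in neutrophils, had a log2 difference of 0.31 with an upper 95% bound of 0.792, and Cxcr2 was above the floor on 1 of 2 knockout-labelled arrays. Trib1 deficiency may raise C/EBP targets beyond Ptges, Lcn2, Arg1 and Serpinb2, and this stays undecided. Camera with an estimated correlation gave the other 9 an adjusted p = 0.3975. The adjustment gave other lists the same value, so it does not gauge these 9 alone, and the test rests on 2 residual degrees of freedom.

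Interferon-stimulated genes had lower means on the knockout-labelled arrays in 32 of 32 members. Across them the genotype difference followed the difference of wild type 1 and wild type 2 with Spearman rho = 0.5649, against 0.155 over other genes, which array-to-array variation of the interferon response needs. Both measures share the wild-type arrays, and a weaker response of the knockouts might give such a rho too. Medians within genotypes were -0.59 (wild type 1 minus 2) and -0.96 (knockout 1 minus 2), larger than the -0.46 between them, and followed each other with rho = 0.79, but a shift shared by both numbers cancels in the genotype means. For Trib1 deficiency, the median was -0.2946 in the arrays numbered 2 and -0.56 in those numbered 1, with 30 and 29 of 32 genes lower, so both explanations stay open.

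Of 10 eosinophil and mast cell markers, 4 passed lower on the knockout-labelled arrays, adjusted over the list alone. The list did not pass camera with an estimated correlation, which rests on 2 residual degrees of freedom, or fry. A purer macrophage preparation there needs markers of other cells to fall alike. The median of stromal markers lay 1.356 log2 units above that of the eosinophil and mast cell markers (permutation test over genes, two-sided p = 1e-05, the smallest that 1e+05 permutations can give). That test takes genes as independent, whereas estimated correlations within the lists were 0.28 (stromal) and 0.45 (eosinophil and mast cell). It therefore cannot decide whether the samples differ. B cell markers (median -0.83, or -0.23 with the floor at the 60th percentile) and dendritic cell markers (-0.19, or -0.35) went the way a purer preparation needs, and neutrophil markers (0.46) did not. Fewer mast cells in these samples stay undecided: of 9 mast cell genes outside the list 3 could be tested, Slc18a2, Tph1 and Mcpt2, with a median of -0.09073. The labels give no source or purification of the macrophages, so a difference between preparations and one due to Trib1 stay open.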
